A study of Rattus norvegicus with 10 samples.

How the data were processed

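Liver RNA from 5 EHBR and 5 SD males, all 5 weeks old, was extracted with TRIzol and made into libraries by poly(A) selection with a directional kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.38, FastQC 0.11.7, HISAT2 2.1.0, featureCounts 1.6.3 and the build rn6, with no order or settings. Whether counting used strand is not given in the sources used here, so values of overlapping genes on opposite strands are uncertain, as are those of near-identical gene copies such as the Mup, RT1, Cyp2b, Cyp2c and Sult1c families.

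The authors deposited 3 tables of 32883 genes with 1 column per sample: TPM, in which every column has the same sum, FPKM, and upper-quartile FPKM. The upper-quartile FPKM values are a constant multiple of the FPKM values within each sample. The authors' TPM values are not a rescaling of their FPKM values: of 8131 genes with at least 50 reads in every sample, 225 differed by over 0.3 on the log2 scale, and 49 of these by over 1. The cause of that difference is not given in the sources used here. Groups and numbers came from the sample titles. The labels do not say how the animals were bred or paired, and p-values measure the spread between these samples.

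Whole reads were recovered from the upper-quartile FPKM. For 18036 genes with a value above 0, a length and an upper-quartile count were found under which 100% of values above 0 came out whole within a tolerance of 0.0002 reads. A length was accepted only where this held, so that share is built into the search. The recovered reads added up to at least 99.98% of the totals that FPKM implies, which ranged from 13.8 to 19.6 M per sample. In simulated values with known upper-quartile counts, the step returned the reads of every sample exactly for 99.9% of 1227 genes, with genes of the fewest reads left out. How those counts are found was not simulated. These reads give the depth, a check with reads thinned to the smallest total, and an added alternative with voom, not the main test.

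The main test was fixed before the data were examined: limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with the trend option, for 11083 genes with at least 1 TPM in at least 5 of the 10 samples. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Strain was its 1 factor. Values simulated for 11083 genes, 200 of them changed, were tested in the same way. Of genes changed by 0.5 on the log2 scale, 30% were called in the right direction, 88% at 1, 98% at 2 and 100% at 3, with 5 false calls. The simulated spread was that left after strain and the division into numbers 1 to 3 and 4 and 5 were fitted, and genes were drawn independently. The main test has no term for that division, so these shares can overstate what it finds.

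Gene lists were also fixed before the data were examined. They held 35 lists with 720 distinct symbols, some of them in more than 1 list. Of these symbols, 662 matched a symbol in the files and 58 did not. Lists of other cell types, neighbouring tissues and sample handling were among them. Camera tested each list of at least 3 kept members with the preset correlation of 0.01 between genes, and its adjusted p covers the 35 lists. The estimated correlation and fry were run beside it, and the estimated correlation also within the parts of the series and with the length trend removed, which was added after the data were seen. Camera compares a list with all other genes, while fry asks whether a list moves on balance in 1 direction. Fry called 10 lists.

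The genes named were chosen by a rule fixed before the data were examined. It takes Abcc2, and the 12 genes with the largest log2 difference in each direction among called genes with a mean of at least 5 TPM in the higher strain and no overlap between strains, leaving out placeholder symbols. It also takes, from each list, up to 3 called members with the smallest adjusted p, or the 1 most abundant member where none was called. This gave 75 genes, of which 67 were called. Genes named outside the rule are said to be so.

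The division of the samples into numbers 1 to 3 and 4 and 5 was seen in the data. Fits with a term for it, fits within each part, and fits with a lowess trend on gene length removed from each sample for the 11044 genes with a recovered length were added after the data were seen. Genes near Abcc2 were compared with genes elsewhere by Fisher's exact test, and with windows of the same size centred on every kept gene with at least 20 others in its window. Other alternatives were FPKM and upper-quartile FPKM, a pseudocount of 0.1 or 5, no filter, a mean of at least 5 TPM, quantile normalization, centring on the sample median, sample weights, a robust variance fit, an exact rank-sum test, the replicate number as a block, and leaving out each sample in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and figures. No reference genome was used here, and coordinates are those of the deposited tables.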

Results

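The Eisai hyperbilirubinemic rat (EHBR) is a mutant line that arose in Sprague-Dawley (SD) rats and lacks the canalicular efflux pump Mrp2, the product of Abcc2. It serves as a model of conjugated hyperbilirubinemia. The loss of Mrp2 goes together with strain in these samples. Its effects and those of other strain differences therefore cannot be told apart here. Poly(A) RNA was sequenced from the livers of 5-week-old males, with 5 EHBR and 5 SD samples numbered 1 to 5 in each strain. The SD samples held 17.8, 16.2, 15.6, 19.6 and 19.6 M reads assigned to genes, and the EHBR samples 15.5, 15.6, 17.5, 17.6 and 13.8 M. Levels are given in TPM, a unit that scales transcript levels to the same total in every sample, as mean ± SD. Differences are log2 of TPM + 1, EHBR minus SD, with limma and Benjamini-Hochberg adjustment over the 11083 genes with at least 1 TPM in at least 5 samples. A fold on this scale understates the change of genes with low TPM.

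Within both strains, the samples numbered 4 and 5 stood apart from those numbered 1 to 3. Deviations from the strain mean correlated between strains at 0.05 to 0.40 across genes for samples on the same side of this division, and at -0.37 to -0.09 for samples on opposite sides. Genes are not independent replicates, so these correlations describe the samples only. Mitochondrial transcripts made up 13.0% to 13.4% of TPM in SD samples 1 to 3 and 17.0% to 17.4% in SD samples 4 and 5, against 14.1% to 15.3% and 15.1% to 16.2% in the EHBR samples. Ribosomal protein genes took 2.3% to 2.6% of TPM in samples 1 to 3 of both strains and 3.2% to 4.5% in samples 4 and 5. Both strains hold the same numbers, so this division is balanced between them. It was found in the data, and strain differences are given within each part where they are printed as pairs.

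Abcc2, which encodes the pump that EHBR lacks, was lower in all 5 EHBR samples than in any SD sample. It lies on chromosome 1 from 263554453 to 263613252 in the build rn6. The SD samples showed 199, 224, 271, 60.0 and 66.4 TPM, and the EHBR samples 17.2, 17.6, 12.3, 11.9 and 10.1 TPM. Abcc2 fell by 3.25 on the log2 scale (SE 0.41, adjusted p = 0.000996, limma). The difference was -3.80 among samples 1 to 3 and -2.42 among samples 4 and 5. Abcc3, the basolateral pump Mrp3 that carries bilirubin glucuronides back to blood, rose from 0.574 ± 0.16 to 4.29 ± 1.03 TPM (SD, n = 5 per strain). Its log2 difference was 1.73 (SE 0.16, adjusted p = 0.00015, limma). Abcc2 and Abcc3 were the 2 of 11 kept efflux pumps that passed the test, and the list as a whole was not called by camera (adjusted p = 0.785).

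**Figure D1:**
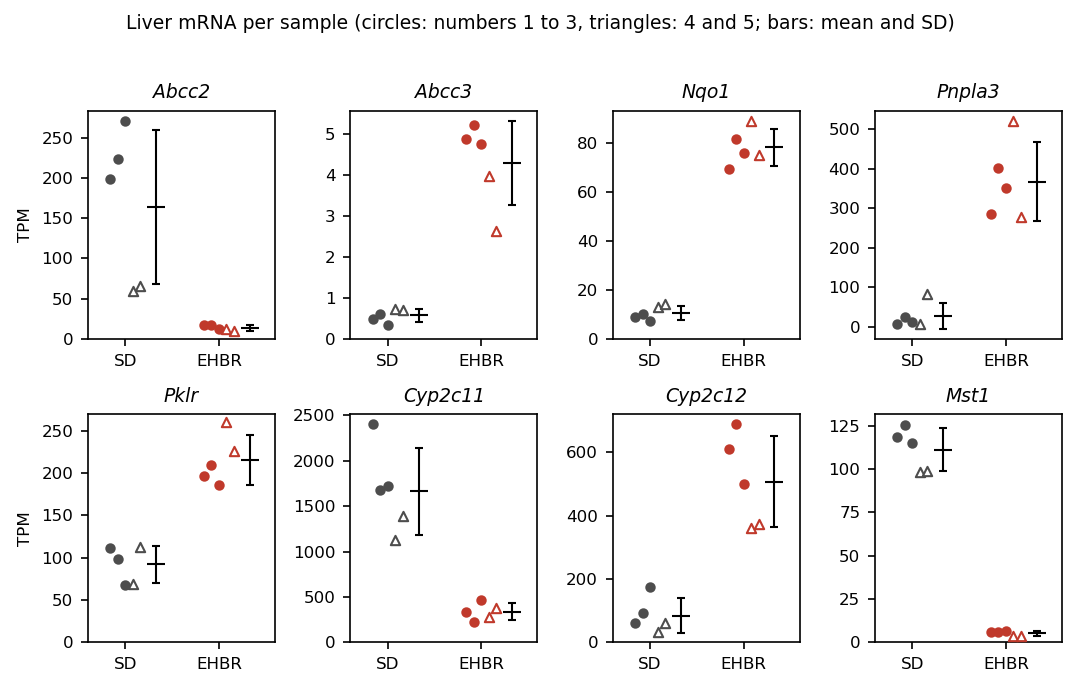
TPM of 8 genes in each of the 5 SD and 5 EHBR livers; circles are samples 1 to 3, triangles are samples 4 and 5, and the bars beside them give the mean and SD. Every EHBR sample lies below every SD sample for Abcc2, Cyp2c11 and Mst1, and above every SD sample for the other 5 genes.

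Over all kept genes, 423 were higher and 181 lower in EHBR at an adjusted p under 0.05. Of these, 109 were at least 2-fold higher and 83 at least 2-fold lower. In 564 of the 604 called genes, every sample of 1 strain lay above every sample of the other, which is likely for genes called on these same samples. Of all kept genes, 939 did so, or 8.47%, where chance gives 0.794%. All 604 kept their sign both among samples 1 to 3 and among samples 4 and 5, which the choice of these genes on the same samples also makes likely. The median kept gene differed by 0.15, and the balance of directions followed the scaling: 70.0% of calls were higher with TPM as deposited. That share was 58.8% with FPKM, 44.1% with upper-quartile FPKM, 52.0% after quantile normalization and 42.0% after each sample was centred on its median, which moved the median gene to -0.02. With a term for the numbers, added after the data were seen, 1506 genes were higher and 372 lower. Strain differences also followed gene length (Spearman correlation 0.255 across genes, a description of these samples). With the length trend removed in each sample, which also centres the samples, 246 genes were higher and 291 lower, and with the term for the numbers as well 572 and 613. The samples numbered 1 to 3 alone gave 482 and 240 genes, and those numbered 4 and 5 alone 460 and 112. Leaving out EHBR sample 1, 2 or 3 left 276, 243 or 269 higher genes. An exact rank-sum test called 0 genes after adjustment and 1756 at an unadjusted p under 0.05, with 0.00794 as the smallest two-sided p that 5 against 5 samples allow.

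Most kept genes of fatty acid synthesis rose in EHBR livers. Of 22 kept members, 14 were higher, none was lower, and 19 were higher when adjusted over the list alone. Pnpla3, a lipase-like lipid droplet protein, rose from 27.0 ± 31.9 to 367 ± 100 TPM (SD, n = 5 per strain), a log2 difference of 4.27 (SE 0.53, adjusted p = 0.000986, limma). Pklr, liver pyruvate kinase, rose from 92.2 ± 22.1 to 216 ± 29.1 TPM. Acacb, an acetyl-CoA carboxylase, rose from 15.0 ± 2.72 to 30.6 ± 3.97 TPM. The list was called as higher (camera, adjusted p = 5.95e-11), with an adjusted p = 0.0731 with an estimated correlation. In glucose metabolism, 3 of 18 members were higher: Pklr, Gpi at 146 ± 14.1 against 82.7 ± 20.8 TPM, and glycogen synthase Gys2 at 48.8 ± 5.78 against 26.8 ± 5.98 TPM. Adjusted over the list alone, 8 members were higher. Gpi lost its call after median centring (log2 0.67 against 0.84) and with the length trend removed (0.69). That list had an adjusted p = 0.00658 by camera and an adjusted p = 0.166 with an estimated correlation, and it was called among samples 1 to 3 (adjusted p = 0.00216, adjusted p = 0.239 with an estimated correlation) and not among samples 4 and 5 (adjusted p = 0.151), with median log2 differences of 0.41 and 0.39.

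Several targets of Nrf2, the transcription factor of the antioxidant response, were higher in EHBR. Of 29 kept members, 10 rose, none fell and 19 did not pass, and 17 rose when adjusted over the list alone. Nqo1, a quinone reductase, went from 10.8 ± 2.85 to 78.3 ± 7.50 TPM, a log2 difference of 2.78 (SE 0.16, adjusted p = 2.39e-06, limma). Ephx1, microsomal epoxide hydrolase, went from 791 ± 108 to 1502 ± 129 TPM. The list also holds Abcc3. Camera called the list at an adjusted p = 9.16e-05, and at an adjusted p = 0.0374 with an estimated correlation, which became an adjusted p = 0.107 with the term for the numbers. Of 31 glutathione genes, 5 were higher and 1 lower (9 and 1 adjusted over the list alone), among them the transferase Gstm4, glutathione synthetase Gss and glutathione reductase Gsr with log2 differences of 0.65, 0.80 and 0.45. Gss and Gsr lost their call when samples were centred on their medians (log2 0.63 and 0.28), and the list was not called (adjusted p = 0.82). The list of targets of the aryl hydrocarbon receptor (AhR) kept 6 members, among them the receptor gene Ahr itself. Of its other members, named outside the rule, Cyp1a1, Cyp1b1, Ahrr and Aldh3a1 were not kept, and Cyp1a2 did not pass (log2 0.41, adjusted p = 0.254, limma). The AhR list was called as higher (adjusted p = 0.0366 by camera, adjusted p = 0.226 with an estimated correlation), with Nqo1, also in the Nrf2 list, and Ugt1a6 as the 2 members that rose and 3 that rose when adjusted over the list alone. That call was lost with the term for the numbers (adjusted p = 0.0694) and among samples 1 to 3 (adjusted p = 0.169), and held among samples 4 and 5 (adjusted p = 0.0144, adjusted p = 0.587 with an estimated correlation), with median log2 differences of 0.19 and 0.81.

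Several liver genes known for higher expression in male rats were lower in EHBR, and several known for higher expression in females were higher. Of 15 male-biased genes, 7 fell and 1 rose, and 9 and 1 did so adjusted over the list alone. Cyp2c11, the main male-specific P450, fell from 1664 ± 480 to 338 ± 94.5 TPM (SD, n = 5 per strain), a log2 difference of -2.30 (SE 0.22, adjusted p = 0.000185, limma). The urinary protein genes Mup5 and Mup4 fell from 1312 ± 764 to 26.4 ± 26.8 TPM and from 130 ± 83.3 to 1.41 ± 1.51 TPM. For Mup5 the difference was -7.72 among samples 1 to 3 and -3.16 among samples 4 and 5, and for Mup4 -7.10 and -3.46. The Mup genes are near-identical copies, so their single values are uncertain. The member that rose was Akr1b7, an aldo-keto reductase, from 2.39 ± 2.42 to 26.3 ± 13.0 TPM. Camera called the list as lower (adjusted p = 1.20e-10), and with an adjusted p = 0.0499 with an estimated correlation.

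Of 12 female-biased genes, 5 rose and none fell, and 7 rose and 1 fell adjusted over the list alone. Among the 5 is Abcc3, also counted above as an efflux pump and an Nrf2 target. Cyp2c12, the female-specific steroid disulfate hydroxylase, rose from 84.2 ± 54.8 to 507 ± 143 TPM, a log2 difference of 2.75 (SE 0.37, adjusted p = 0.0015, limma). Cyp2c7 rose from 753 ± 259 to 2108 ± 227 TPM and the prolactin receptor gene Prlr from 5.30 ± 4.72 to 32.2 ± 3.65 TPM. The list was called as higher (adjusted p = 0.00681 by camera, adjusted p = 0.214 with an estimated correlation). It lost that call with the term for the numbers (adjusted p = 0.0553) and among samples 4 and 5 (adjusted p = 0.154), and held it among samples 1 to 3 (adjusted p = 0.012, adjusted p = 0.439 with an estimated correlation). Its median log2 difference was 0.87 among samples 1 to 3 and 0.83 among samples 4 and 5.

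Drug-metabolising P450 genes were lower as a list, with 6 of 27 members lower and 2 higher, or 11 and 3 adjusted over the list alone. Cyp2b2 fell from 246 ± 71.2 to 56.4 ± 12.3 TPM and Cyp3a62 from 14.8 ± 3.80 to 3.22 ± 1.19 TPM, with Cyp2c11 among the others. The members that rose were Cyp2c7 and Cyp2c12, both also in the female-biased list, and Cyp2c11 is also in the male-biased list. Cyp2b2 and Cyp3a62 are in neither. Camera gave an adjusted p = 7.75e-07, and an adjusted p = 0.0499 with an estimated correlation. Targets of the nuclear receptors CAR and PXR went both ways, with 5 of 26 higher and 5 lower (7 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.0627). Abcc2, the gene of the pump that EHBR lacks, is counted among the 5 lower members, and Abcc3 among the 5 higher.

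Cytosolic sulfotransferases of the Sult1c family fell in EHBR. Sult1c2a went from 58.5 ± 16.1 to 13.2 ± 3.45 TPM, Sult1c3 from 229 ± 73.3 to 73.4 ± 10.1 TPM and Sult1c2 fell by 1.55 on the log2 scale. In the list of 19 sulfotransferases and carboxylesterases, 5 members fell and 2 rose (7 and 3 adjusted over the list alone). Of the 5, Sult1e1, named outside the rule, is also among the lower male-biased genes. Camera called the sulfotransferase and carboxylesterase list as lower (adjusted p = 0.0194, adjusted p = 0.174 with an estimated correlation), although its median log2 difference was 0.13 against a mean of -0.26, and fry did not call it (adjusted p = 0.0854). The call was lost among samples 1 to 3 (adjusted p = 0.0839) and held among samples 4 and 5 (adjusted p = 0.00902, adjusted p = 0.677 with an estimated correlation), with medians of 0.13 and 0.08. Of 7 genes of glucuronidation, 5 of them UDP-glucuronosyltransferases and the others Ugdh and Ugp2, which make their cosubstrate, 2 rose, Ugt1a6 from 69.3 ± 11.5 to 97.7 ± 2.08 TPM and Ugt2a3 from 17.3 ± 6.46 to 31.5 ± 3.41 TPM, and 4 adjusted over the list alone. That list was not called by camera (adjusted p = 0.0516) and was called as higher by fry (adjusted p = 0.000824). Camera called it among samples 1 to 3 (adjusted p = 0.00848, adjusted p = 0.239 with an estimated correlation) and with the term for the numbers (adjusted p = 0.0478, adjusted p = 0.289 with an estimated correlation). Both genes lost their call after median centring, at 0.34 and 0.72 on the log2 scale against 0.51 and 0.89. The Ugt1a exons are shared between transcripts, and the gene listed as Ugt1a6 spans 95161157 to 95302822 on chromosome 9. Its value may therefore include other Ugt1a transcripts. Ugt1a1 was not among the matched members of that list or the kept genes, so its own level is not known here.

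In the test without a term for the numbers, genes that handle bilirubin, bile acids and their uptake showed few differences. With that term, 5 heme and bilirubin genes were higher and 2 lower, 2 bile acid genes were higher, and 4 uptake carriers were higher and 1 lower. Of all 11083 kept genes, 1506 were higher and 372 lower with it. None of these 3 lists was called by camera with it. Of 21 genes of heme breakdown and bilirubin handling, 2 rose and 1 fell (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.785). Gsta3 rose from 51.8 ± 47.5 to 216 ± 78.4 TPM, Blvrb, a biliverdin reductase, from 136 ± 7.69 to 171 ± 8.60 TPM, and the heme-binding protein gene Hpx fell from 6862 ± 1080 to 4792 ± 326 TPM. With FPKM, Gsta3 lost its call (adjusted p = 0.0551) at a log2 difference of 2.39 against 2.53 with TPM, and Blvrb (adjusted p = 0.339) at 0.16 against 0.32. Hpx lost its call after quantile normalization, at -0.23 against -0.51. None of 18 bile acid synthesis genes passed, also when adjusted over the list alone, and the most abundant, the conjugating enzyme gene Baat, had 1102 ± 169 TPM in SD and 932 ± 106 TPM in EHBR (list adjusted p = 0.82). Of 16 sinusoidal uptake carriers, Slc22a25 rose by 0.91 and Slc29a1 fell by 0.88 on the log2 scale (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.404).

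In cholesterol synthesis, Hmgcs1 and Idi1 fell by 1.24 and 0.84 on the log2 scale, while Insig1, which restrains that pathway, rose from 140 ± 47.7 to 386 ± 144 TPM. The other 22 of 25 members did not pass the test. Adjusted over the list alone, 4 rose and 2 fell, and the list was not called (adjusted p = 0.201), although it was called as lower among samples 1 to 3 (adjusted p = 0.00996, adjusted p = 0.517 with an estimated correlation) and not among samples 4 and 5 (adjusted p = 0.65). Of 32 PPARa targets and fatty acid oxidation genes, 2 fell, also when adjusted over the list alone: the omega-hydroxylase gene Cyp4a2, from 535 ± 334 to 14.6 ± 5.65 TPM, and the thiolase gene Acaa2, from 728 ± 222 to 329 ± 28.6 TPM. Cyp4a2 is also among the lower male-biased genes. The PPARa list was not called (adjusted p = 0.0657), but it was called as lower among samples 4 and 5 (adjusted p = 1.03e-07, adjusted p = 0.587 with an estimated correlation, median log2 difference -0.14) and not among samples 1 to 3 (adjusted p = 0.0653, median 0.20). ER stress genes were called as lower relative to all other genes (adjusted p = 0.00658 by camera, adjusted p = 0.174 with an estimated correlation) with a median log2 difference of 0.03 over 25 members, a call lost with the length trend removed (adjusted p = 0.0524). Fry did not call that list (adjusted p = 0.414). The 2 that fell, also when adjusted over the list alone, were Dnajc3 and Sdf2l1, by 0.38 and 1.06 on the log2 scale.

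**Figure D2:**
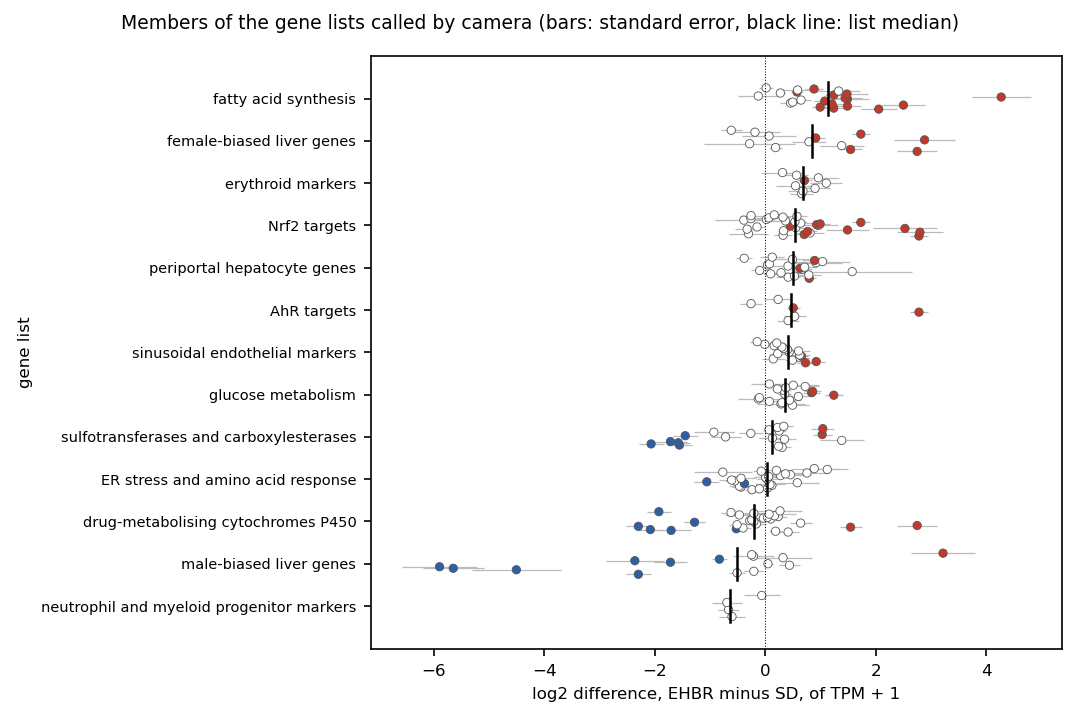
Log2 difference of TPM + 1, EHBR minus SD, for each kept member of the 13 lists called by camera with its preset correlation; red and blue points passed the gene test as higher or lower, open points did not, bars are standard errors and the black line is the list median. Fatty acid synthesis has 14 of 22 members higher in EHBR and the male-biased list 7 of 15 lower.

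Several of the largest single-gene differences lay outside these lists. Acnat1, a peroxisomal acyl-CoA N-acyltransferase gene on chromosome 5 from 64713443 to 64718131, had 175 ± 81.2 TPM in SD and 0.0834 ± 0.0863 TPM in EHBR (SD, n = 5 per strain). Its neighbour Acnat2 had 66.8 ± 52.5 and 3.18 ± 0.88 TPM. The MHC class I gene RT1-N2 and the lectin gene Reg4 had 35.8 ± 7.73 and 15.7 ± 3.21 TPM in SD and are listed at 0 in all 5 EHBR samples. Mst1, which encodes macrophage-stimulating protein, fell from 111 ± 12.2 to 5.19 ± 1.38 TPM (log2 -4.21, SE 0.16, adjusted p = 4.28e-08, limma). Ephx2, soluble epoxide hydrolase, fell from 34.3 ± 17.7 to 2.90 ± 0.62 TPM. Nox4, an NADPH oxidase gene, fell from 10.4 ± 7.64 to 0.432 ± 0.14 TPM, by -3.48 on the log2 scale among samples 1 to 3 and by -1.33 among samples 4 and 5. Hamp, which encodes the iron hormone hepcidin, had 2418 ± 1281 TPM in SD and 186 ± 189 TPM in EHBR (log2 -5.06, adjusted p = 0.04). Its difference was -3.54 among samples 1 to 3 and -7.33 among samples 4 and 5, and its call was lost in 13 alternatives, quantile normalization among them (log2 -4.98, adjusted p = 0.0503).

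Among the largest rises, Ifit1, an interferon-induced gene on chromosome 1 from 252944103 to 252946170, had 15.2 ± 5.70 TPM in EHBR and is listed at 0 in all 5 SD samples. Pnpla5 and Sult4a1, which lie next to Pnpla3 on chromosome 7, had 40.7 ± 7.18 and 6.38 ± 1.47 TPM in EHBR against 5.79 ± 9.45 and 0.148 ± 0.22 TPM in SD. Aldh1a7 had 66.0 ± 16.9 against 8.05 ± 7.28 TPM, with a log2 difference of 2.03 among samples 1 to 3 and 5.77 among samples 4 and 5. Rgs16, a regulator of G protein signalling, had 25.5 ± 17.9 against 1.86 ± 1.59 TPM. Lcn2, lipocalin 2, had 8.28 ± 2.63 against 0.151 ± 0.16 TPM. Lcn2 was the 1 of 22 acute phase genes that rose, with Hamp and Hpx lower (1 and 3 adjusted over the list alone), and that list was not called (adjusted p = 0.119). Ifit1 and Rsad2 (0.75 on the log2 scale) were the 2 of 31 interferon genes that rose, also when adjusted over the list alone, and that list was not called (adjusted p = 0.562). Rsad2 lost its call with FPKM (log2 0.51, adjusted p = 0.0775).

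A few markers of other liver cells and of position in the lobule differed between the strains. Of 17 sinusoidal endothelial markers, 3 rose (9 adjusted over the list alone): Stab2, Kdr and Stab1 with log2 differences of 0.92, 0.66 and 0.73 (adjusted p = 0.00225 by camera, adjusted p = 0.423 with an estimated correlation). Of 9 erythroid markers, Slc4a1 rose from 1.22 ± 0.25 to 2.64 ± 0.50 TPM and 7 rose adjusted over the list alone (adjusted p = 0.00546 by camera, adjusted p = 0.226 with an estimated correlation). The 4 kept neutrophil markers were called as lower (adjusted p = 0.00225 by camera, adjusted p = 0.166 with an estimated correlation) although none passed over all genes and 3 did adjusted over the list alone. S100a9 had 4.07 ± 1.13 TPM in SD and 2.19 ± 0.61 TPM in EHBR. Of 20 periportal genes, Ass1, Gls2 and Etnppl rose, with Ass1 at 1730 ± 190 against 997 ± 119 TPM, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.0366 by camera, adjusted p = 0.676 with an estimated correlation). Gls2 and Etnppl lost their call with FPKM (adjusted p = 0.0584 and 0.0991), at 0.53 and 0.76 on the log2 scale against 0.63 and 0.89 with TPM. Kdr and Stab1 lost theirs after median centring (log2 0.49 and 0.56), and with the length trend removed Stab2, Kdr, Stab1 (log2 0.69, 0.43 and 0.50) and the endothelial list (adjusted p = 0.0515) were not called. Among samples 4 and 5 alone, none of these 4 lists was called, with an adjusted p = 0.743 for endothelial, 0.851 for erythroid, 0.154 for neutrophil and 0.247 for periportal genes, while all 4 were called among samples 1 to 3. Those calls were lost with an estimated correlation, at an adjusted p = 0.439, 0.272, 0.239 and 0.372 in the same order. Median log2 differences among samples 1 to 3 and among samples 4 and 5 were 0.41 and 0.31 for endothelial, 1.01 and 0.33 for erythroid, -0.78 and -0.31 for neutrophil and 0.57 and 0.47 for periportal genes. Over all samples, fry called the endothelial and erythroid lists (adjusted p = 0.00895 and 0.00691). It did not call the neutrophil and periportal lists (adjusted p = 0.0504 and 0.0559).

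The remaining cell type lists were not called by camera in the main fit of all samples. The macrophage marker Mrc1 rose from 4.37 ± 0.44 to 11.8 ± 1.87 TPM, the 1 of 15 Kupffer cell markers to pass (list adjusted p = 0.516). No member passed among 8 bile duct markers (adjusted p = 0.644), 20 stellate cell and matrix genes (adjusted p = 0.368), 9 lymphocyte markers (adjusted p = 0.0608), 23 cell cycle genes (adjusted p = 0.0516) and 16 pericentral genes (adjusted p = 0.126). Within the parts, cell cycle genes were called as higher among samples 4 and 5 (adjusted p = 0.000132, adjusted p = 0.587 with an estimated correlation, median log2 difference 0.87, 6 members higher) and not among samples 1 to 3 (adjusted p = 0.705). Camera also called them as higher with the length trend removed (adjusted p = 0.00506, adjusted p = 0.654 with an estimated correlation) and with the replicate number as a block (adjusted p = 0.0477). Lymphocyte markers (adjusted p = 0.0426, adjusted p = 0.336 with an estimated correlation) and pericentral genes (adjusted p = 0.0302, adjusted p = 0.239 with an estimated correlation) were called as lower among samples 1 to 3 alone. The most abundant of the genes in these lists, Slc4a2, Fn1, Coro1a, Pcna and Cyp2e1, had log2 differences of 0.16, 0.01, -0.35, 0.30 and -0.04. Among 3 kept genes of neighbouring tissues, the pancreatic carboxypeptidase gene Cpb1 rose from 0.540 ± 0.25 to 3.03 ± 0.70 TPM and the elastase gene Cela1 fell from 52.6 ± 9.32 to 25.9 ± 4.08 TPM (list adjusted p = 0.777).

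Lists on sample handling and minerals were not called either. None of 17 clock genes passed (adjusted p = 0.944) in the test without a term for the numbers, and Dbp had 75.1 ± 67.9 TPM in SD and 103 ± 90.5 TPM in EHBR, with most of that spread between samples 1 to 3 and samples 4 and 5. With the term for the numbers, 4 clock genes were higher and none lower in EHBR (list adjusted p = 0.276): Per1, Cry2, Tef and Ciart, named after their values were seen. The heat shock gene Hspb1 fell from 23.4 ± 14.6 to 6.69 ± 0.47 TPM, the 1 of 19 immediate early and heat shock genes to pass (list adjusted p = 0.0627). The zinc carrier gene Slc39a4 rose by 1.25 on the log2 scale, and with Hamp it was 1 of 2 to pass among 17 metallothionein and iron genes (list adjusted p = 0.82). Of 13 mitochondrially encoded genes only Mt-atp8 passed, with a log2 difference of 0.59 (list adjusted p = 0.644). It overlaps Mt-atp6 and lost its call with FPKM (log2 0.09, adjusted p = 0.746). The list was called as lower among samples 4 and 5 (adjusted p = 0.00388, adjusted p = 0.587 with an estimated correlation) and not among samples 1 to 3 (adjusted p = 0.257).

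In all, 13 of the 35 lists were called by camera with its preset correlation of 0.01, 8 as higher and 5 as lower. Of these 13, fry did not call the ER stress, sulfotransferase, neutrophil and periportal lists. With a correlation estimated for each list, the Nrf2, male-biased and P450 lists were called, and with the term for the numbers as well, none was called (smallest adjusted p = 0.107). None was called with an estimated correlation among samples 1 to 3 (smallest adjusted p = 0.0536), among samples 4 and 5 (smallest adjusted p = 0.587) or with the length trend removed (smallest adjusted p = 0.114). Of 100 regroupings of the 10 samples into 5 and 5, 13 called at least 13 lists, the real grouping included. These regroupings were not kept balanced over the numbers 1 to 3 and 4 and 5, so some follow that division. Relabelling within the parts was not run for lists, so chance cannot be excluded for this count.

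The neighbourhood of Abcc2 was examined because a stretch of chromosome around the mutated gene can differ between related strains. Within 10 Mb of Abcc2, 13 of 103 other kept genes were called, or 12.6%, against 590 of 10979 elsewhere, or 5.37% (two-sided Fisher's exact test p = 0.00379, odds ratio 2.54). That test treats neighbouring genes as independent, which they are not, so its p is too small. The 13 hold members of the same families, Cyp2c11, Cyp2c24 and Cyp2c12, and Scd and Scd2. This share lay above that of 96.8% of the windows of the same size along the genome. At 5 Mb and 20 Mb, 10 of 83 and 18 of 184 genes were called, above 94.6% and 94.1% of windows. The called genes there include Cyp2c11, Cyp2c12 and Scd, a desaturase gene of fatty acid synthesis that was named after its values were seen. Scd had 2670 ± 260 TPM in EHBR and 557 ± 318 TPM in SD (log2 2.50, SE 0.39, adjusted p = 0.00323, limma), with a log2 difference of 1.75 among samples 1 to 3 and 3.62 among samples 4 and 5.

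**Figure D3:**
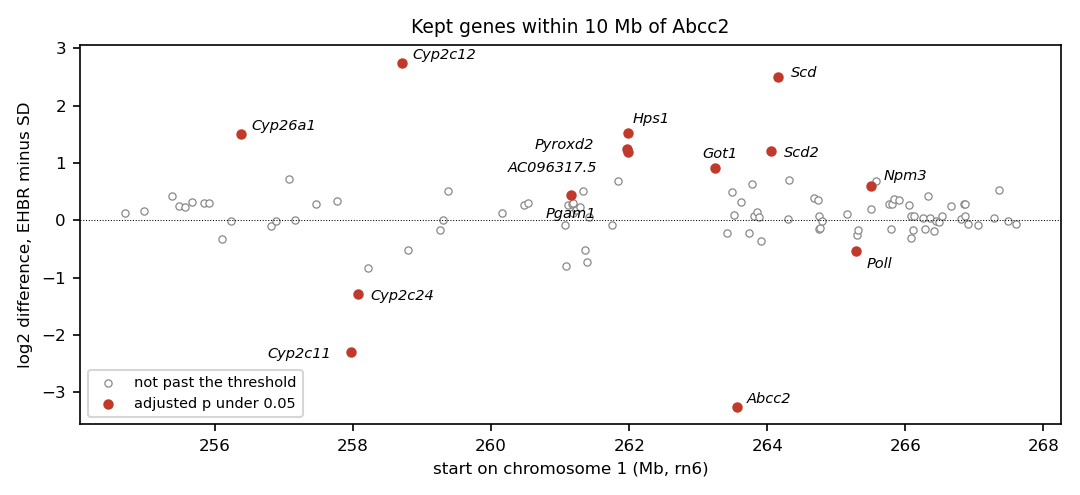
Log2 difference of TPM + 1, EHBR minus SD, of each kept gene within 10 Mb of Abcc2, against its start on chromosome 1 in megabases of rn6; filled points passed the test. The 13 called neighbours lie on both sides of Abcc2 and go in both directions.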

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

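The tests of time of day and read depth, of strain differences between the parts of the series, and the splits with a term for the numbers were chosen only after the data were seen.

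The samples numbered 4 and 5 stood apart from those numbered 1 to 3 in both strains, a division no label names. Among 17 kept clock genes, 10 had no overlap between these samples, 9 lower and 1 (Arntl) higher in samples 4 and 5, or 58.8% against 17.4% of 11066 other genes (one-sided Fisher's exact test p = 0.000152). Dbp, a clock output gene, had 93.8, 152, 121, 4.42 and 4.06 TPM in SD samples 1 to 5 and 186, 146, 173, 3.26 and 7.51 TPM in EHBR samples 1 to 5. A trend with gene length, whose removal moved the number of genes called between the parts from 4181 to 2119, is excluded as the whole cause, since the lowest correlation within a part was 0.0579 after its removal and the highest across parts -0.0812, and depth is excluded, since with reads thinned to 13.8 M in every sample these values were 0.0648 and -0.0877. Collection at another hour could account for the division, a hypothesis that the clock genes fit, but feeding, litter and a separate batch of libraries stay open, and no label gives a group that could test them.

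The strain difference itself differed between these parts in 30 genes, 23 with a more positive and 7 with a more negative value in samples 4 and 5 (limma interaction test). Among the named genes, the log2 difference was more positive in samples 4 and 5 by 3.74 for Aldh1a7, by 4.56 for Mup5, by 3.64 for Mup4 and by 2.16 for Nox4. For Scd, named outside the rule, it was more positive by 1.87 (adjusted p = 0.0438).

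In 10 of 153 sets of 5 values, 1 sample lay far from the rest, where chance alone gives about 1 in 20, or 7.65. The gap to the nearest sample, as a share of the whole range on the log2 scale, was 0.92 for Pnpla5 in SD (sample 5 at 22.7 TPM, the others at 1.34 to 1.81) and 0.721 for Sult4a1 in SD (sample 5 at 0.541, the others at 0 to 0.128). It was 0.79 for Cyp4a2 in SD (sample 2 at 25.1, the others at 431 to 912), 0.746 for Insig1 in SD (sample 2 at 224, the others at 111 to 133), 0.879 for Baat in SD (sample 5 at 802, the others at 1154 to 1214) and 0.807 for Hspb1 in SD (sample 1 at 49.3, the others at 15.1 to 19.1). In EHBR it was 0.867 for Hpx (sample 5 at 4214, the others at 4871 to 4981), 0.839 for Ugt1a6 (sample 5 at 101, the others at 96.4 to 97.2), 0.757 for Gss (sample 4 at 81.9, the others at 62.5 to 66.8) and 0.729 for Sdf2l1 (sample 4 at 64.8, the others at 34.8 to 41.2).

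Other groupings of the same 10 samples bear on the counts. Of 100 splits into 5 and 5, 2 gave at least 604 called genes, the real one included, and the highest other gave 827, with SD sample 1 joined to all 4 samples numbered 4 and 5. Of 60 relabellings within the parts, fitted with the term for the numbers, 1 gave at least the real count of 1878, which was the real one, and the highest other gave 2. For differences of at least 2-fold, 1 of 100 splits reached the real count of 192, again the real one, and the highest other gave 117. For lists, 13 of 100 splits called at least the real 13, with 17 as the highest other. Some of these splits follow the division into parts, and relabelling within the parts was not run for lists. Chance therefore stays open for the number of lists. With an estimated correlation, 2 of 100 splits called at least the real 3 lists, with 3 as the highest other.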

How the results depend on the processing

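The term for the numbers (1 to 3 against 4 and 5), both voom fits on whole reads, both fits on parts of the series, the rescaled upper-quartile values, the removal of the length trend and the estimated correlation joined to any of these were chosen after the data were seen. Direction is read only where a test passes.

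The exact rank-sum test, run for counts only, called no gene (smallest adjusted p 0.0937), Abcc2 included. In every other alternative Abcc2 kept its call, with log2 differences from -3.80 to -2.42 and a highest adjusted p of 0.00444. Of 67 called named genes, 57 were tested in all 29 alternatives other than the rank-sum test, and 26 of these kept their call in each. The called named genes not tested in all 29 fell under the filter of a mean of 5 TPM. Calls were lost most often for Etnppl (20 alternatives) and Mt-atp8 (18), and by setting with samples 4 and 5 alone (28 genes), which leaves fewer samples, and upper-quartile FPKM (22). Over all named genes, 1916 results were the same, 214 weaker, 4 stronger and 1 reversed: Fn1, not called in the main test, at -0.23 with the number term and no length trend (adjusted p = 0.0446). For lists, 742 were the same, 91 weaker, 40 stronger and 2 reversed: erythroid markers in samples 4 and 5 alone, with an adjusted p = 0.851, and 0.92 with an estimated correlation, which are no calls.

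Higher genes went from 423 to 190 with upper-quartile FPKM, 219 with those values rescaled, 193 after median centring, 719 with sample weights, 639 with the replicate block, 1506 with the number term, 246 without the length trend, 879 with voom and the number term, and 0 by rank-sum, where 5 against 5 samples limit the p. Lower genes went from 181 to 290 after quantile normalization, 292 with sample weights, 372 with the number term, 291 without the length trend, 613 with both, 112 in samples 4 and 5 alone, 462 with voom and the number term, and 0 by rank-sum. Genes at least 2-fold higher went from 109 to 69 with FPKM, 63 with rescaled upper-quartile FPKM, 52 with a pseudocount of 5, which shrinks folds of low genes, 66 after median centring and 279 in samples 4 and 5 alone. Those at least 2-fold lower went from 83 to 53 with that pseudocount and 133 with voom and the number term. Leaving out 1 sample gave 243 to 439 higher and 135 to 179 lower genes. The lists went from 13 to 3 with an estimated correlation and 0 with that and the number term, a part of the series alone or no length trend. Where no reason is given, the cause was not tested.

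The samples share only a number: the block gave 639 higher and 222 lower genes, same-number correlations ran from 0.0742 to 0.287, and 4 of 10 samples correlated best with their own number. The block moved AhR targets to an adjusted p = 0.0808 and cell cycle genes to 0.0477. Depth of 13.8 to 19.6 M reads leaves genes near 1 TPM the least precise.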

Other observations

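The tests for females among the samples and for the parts of the series, and the choice of the RT1, Akr1c and Y-linked genes, were made only after values were seen.

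Classical and nonclassical MHC class I genes of the RT1 complex on chromosome 20 differed between the strains in both directions. Of 17 kept RT1 genes, 5 were lower in EHBR and 2 higher. RT1-CE5 fell from 15.3 ± 3.87 to 2.03 ± 0.46 TPM (SD, n = 5 per strain; log2 -2.40, adjusted p = 2.56e-05, limma) and RT1-CE4 by 1.95 on the log2 scale, while RT1-CE7 rose by 1.17 and RT1-T24-4 by 1.08. These genes share reads, so single values are uncertain.

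On the Y chromosome, Kdm5d, a histone demethylase gene, fell from 2.56 ± 0.57 to 0.656 ± 0.17 TPM (adjusted p = 0.00151, limma). On chromosome 17, the aldo-keto reductase genes Akr1c2, Akr1c1, Akr1c13 and Akr1c12 had log2 differences of -2.25, -2.04, -1.22 and -0.70 (adjusted p = 0.00323, 0.00499, 0.000734 and 0.01, limma).

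In EHBR, 7 of 15 male-biased liver genes were lower, and 5 of 12 female-biased genes higher, a list whose call was lost with the term for the numbers (adjusted p = 0.0553) and with an estimated correlation (adjusted p = 0.214). Livers of females are excluded, since the Y-linked gene Eif2s3y had at least 23.4 TPM in every EHBR sample and at least 20.4 TPM in every SD sample. The Mup copies are excluded as the whole cause of the male-biased part, since the other 13 members, 5 of them lower, were still called as lower (camera, adjusted p = 8.70e-07), although with an adjusted p = 0.0682 with an estimated correlation. Samples 4 and 5 are excluded as its source, since the median log2 difference of the list was -1.03 among samples 1 to 3. A strain difference in sexual maturation or hormone signalling at 5 weeks stays open as an untested hypothesis.

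In 5 genes, 1 strain lay at or under 0.1 TPM in all 5 samples while the other averaged at least 5 TPM: Reg4, RT1-N2, RGD1560242 and AABR07048439.1 near 0 in EHBR, and Ifit1 near 0 in SD. A failed estimate in the TPM file is excluded, since 5 of 5 had under 10% of the other strain's recovered reads, for example 0 against 4506 for RT1-N2 and 2 against 1742 for Ifit1. In 0 of the 3 with named relatives did the relatives, summed, gain the level lost. Their sum in the strain near 0 was higher by 0.117 TPM for Reg4 and 10.9 TPM for RT1-N2, and lower by 5.19 TPM for Ifit1. The levels lost were 15.7, 35.8 and 15.2 TPM. A sum cannot exclude reads counted for a single relative, since falls can offset gains. Of 17 kept RT1 genes, 2 were higher in EHBR, RT1-T24-4 (17.9 to 37.6 TPM) and RT1-CE7 (10.2 to 23.2 TPM), and 5 lower, among them RT1-A2 (54.6 to 26.7 TPM). Absence of the transcript, strain variants that keep reads from aligning to the reference and reads counted for a relative stay open, as reads were not analysed here.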
